A study of Mus musculus with 6 samples.

How the data were processed

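Perigonadal white adipose tissue of mice (6 samples) was profiled by paired-end RNA sequencing of total RNA, per the labels' protocols. Whether the libraries keep the strand is not given in the sources used here. The labels put 3 libraries in the flox control group (replicates 282, 369 and 485) and 3 in the adipose Rab10 knockout group (replicates 302, 341 and 466), where the numbers are those in the sample titles. The labels call the flox tissue female and give an age of about 28 weeks for the knockout tissue only. They do not say outright that each number is a separate animal, so the p-values measure only the spread between these samples, which may in part be technical.

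The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), with 1 value per gene symbol and library. Reads were processed with TopHat and Cufflinks against the mouse build mm9, per the submitters' processing notes. The versions of these tools, the gene annotation, the normalization setting and the part of Rab10 that was deleted are not given in the sources used here. Each file held 22026 genes, of which 6979 were listed at 0 in all 6 libraries. The FPKM summed to between 2300533 and 2549238 per library, and between 14037 and 14468 genes were above 0. No counts were used here and whole reads could not be recovered from the values, so the depth of each library is unknown and no counting interval is given. Of the 22026 symbols, 19800 matched the supplied mouse gene names. The supplied genome is a later build (GRCm38) than that of the files, so no coordinates are printed.

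Values were transformed as log2(FPKM + 1), so a fold change on this scale understates the change of genes with low values. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which left 14038. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Ratios are ratios of mean FPKM. In all, 37 gene lists (pathways, cell type markers and checks) were fixed, and the 33 with at least 5 tested members, leaving out the list of sex-linked genes, were tested as sets with limma's camera at its preset correlation of 0.01, adjusted over the 33 lists. Camera with a correlation estimated for each list and limma's fry were run beside it. Members of a list were also adjusted over the list alone. The score of a list in a library is the mean over its members of log2(FPKM + 1) minus the mean of the 6 libraries.

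The groups, the tests, the gene lists, the alternatives to be tried and the rule for named genes were fixed before the data were examined. The rule takes Rab10, Rab8a, Rab8b, Rab13, Rab14, Slc2a4 and Tbc1d4. It adds the genes past the threshold and, where fewer than 10 pass, the genes with the smallest unadjusted p until there are 10 per direction. It also takes up to 3 members of each list with the smallest p, and for cell type lists the member with the highest mean. Predicted genes without a name were left out: 2 among those higher in knockout and 0 among those lower. The rule covers 137 genes, of which the text prints those of the groups it describes; C1qtnf5, Prr7 and 2410076I21Rik stand outside the rule and were named after their values were seen. Some genes that the rule takes are not reported here.

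The steps were tested on simulated data made from these libraries. With 100 genes changed 2-fold and 100 changed 4-fold among 14038 genes in the knockout against flox comparison, 61 and 86 were recovered, with 4 false calls. A shift of 0.5 on the log2 scale in the T and NK cell list was called. The changed genes were drawn only from those whose mean log2(FPKM + 1) exceeded the value for 5 FPKM. The simulated noise was independent between genes and between libraries. The counts recovered thus do not cover genes with lower values and do not measure the power in these data. Nor does the simulation test the preset correlation on lists whose members move together. The alternatives tried were a pseudocount of 0.1 FPKM, no filter on low values, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, leaving out each library in turn, limma without the trend, with robust moderation or with array weights, an immune marker score as covariate, leaving out sex-linked markers, and an adjusted p threshold of 0.1. The library set, which is the side of the first principal component on which a library lies, was added as a covariate after the data were seen. Figures were drawn with matplotlib 3.10.9.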

Results

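Gene expression was measured in 3 samples of perigonadal white adipose tissue from flox control mice and 3 from mice with an adipose knockout of Rab10, a small GTPase that takes part in the insulin-regulated movement of the glucose transporter GLUT4 to the cell surface. The series title ties the knockout to insulin resistance and impaired glucose uptake, and the comparison asks which transcripts of the fat depot differ between the genotypes. Values are FPKM, given as mean ± SD with n = 3 libraries per group. All 6 libraries held the X-inactivation RNA Xist, at 238 to 451 FPKM, and 0 of 6 Y-linked genes were above 0 in any of them.

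Rab10 itself was lower in the knockout, at 245 ± 41.3 FPKM against 314 ± 13.9 in flox tissue (SD, n = 3), which is 22.1% less. The flox libraries held 329 (282), 302 (369) and 311 (485) FPKM and the knockout libraries 266 (302), 271 (341) and 197 (466), so that every knockout library lay below every flox library. An exact two-sided permutation test of Rab10 gave p = 0.1, the smallest value that 3 against 3 libraries allow. The log2 fold change was -0.37 (SE 0.14), and it did not pass the threshold over all genes (limma, adjusted p = 0.876). Whole tissue was measured, so transcripts of cells other than adipocytes are part of these values.

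The Rab10 relatives and partners in GLUT4 traffic did not pass the threshold. Rab14, another endosomal Rab, stood at 324 ± 31.3 FPKM in flox and 361 ± 35.5 in knockout tissue (SD, n = 3), Rab8a at 131 ± 17.5 and 138 ± 15.8, Rab8b at 80.1 ± 34.6 and 90.2 ± 29.7, and Rab13 at 103 ± 15.2 and 96.1 ± 11.3. Slc2a4, which encodes GLUT4, was at 251 ± 33.0 and 299 ± 32.0 FPKM. Tbc1d4, the insulin-regulated GTPase-activating protein that acts on Rab10, was at 38.8 ± 2.58 and 45.6 ± 2.62 FPKM. Of the 41 tested members of the GLUT4 traffic list, 0 passed when adjusted over all genes or adjusted over the list alone, and the list did not move as a set (limma camera, adjusted p = 0.777). The insulin signalling list did not move either (limma camera, adjusted p = 0.546), with 0 of 29 members past the threshold when adjusted over the list alone.

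**Figure D1:**
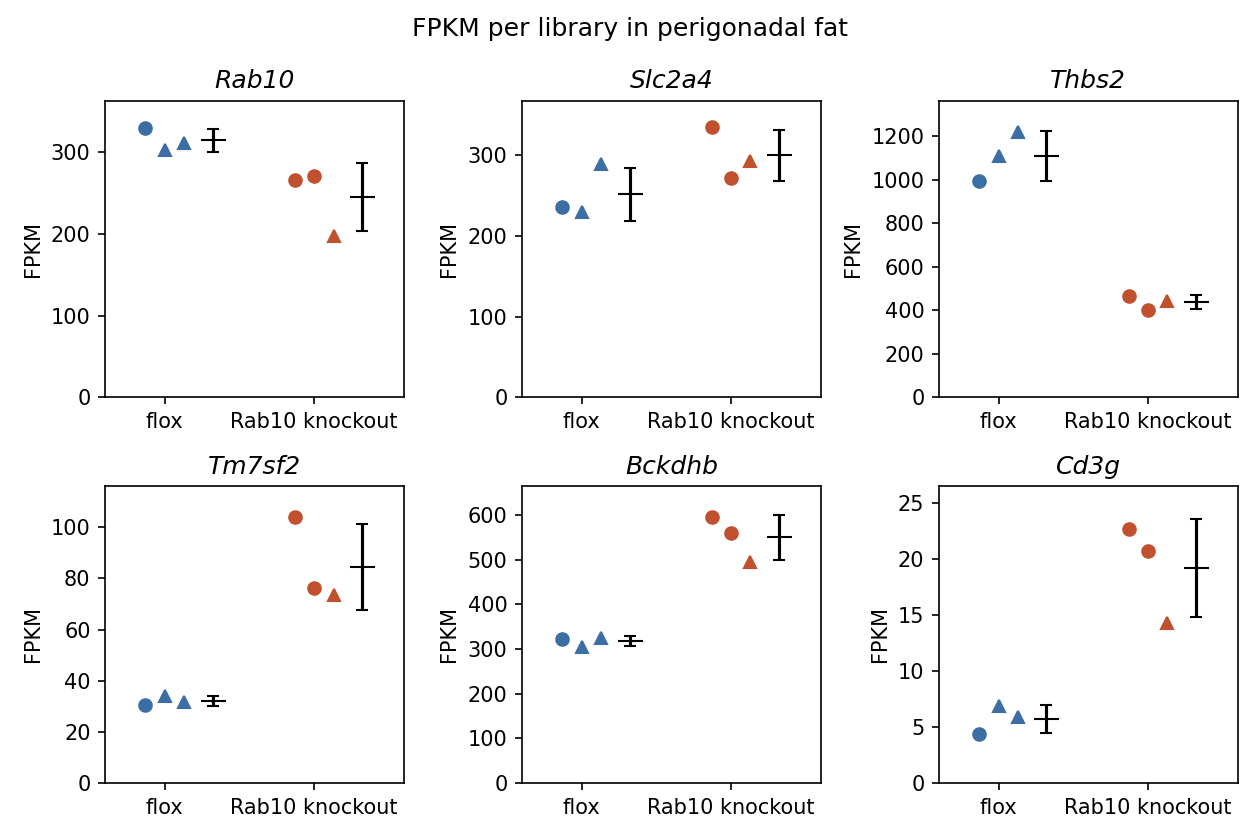
FPKM of 6 genes in each library (points; circles, replicates 282, 302 and 341; triangles, replicates 369, 466 and 485), with the mean and SD of each group of 3 in black; the vertical axes start at 0. Rab10 and Thbs2 lie lower in every knockout library than in any flox library, Tm7sf2, Bckdhb and Cd3g lie higher, and Slc2a4 overlaps.

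The genes with the smallest p lower in the knockout included Thbs2, a matrix glycoprotein, at 437 ± 32.3 FPKM against 1108 ± 114 in flox tissue (SD, n = 3), a 2.54-fold difference. Among genes higher in the knockout were Clstn3, a calsyntenin, at 43.2 ± 5.91 against 16.3 ± 1.81 FPKM (2.65-fold), Tm7sf2, a sterol reductase, at 84.6 ± 16.8 against 32.1 ± 1.87 (2.63-fold), and Slc38a3, a glutamine transporter, at 9.95 ± 1.77 against 1.79 ± 0.434 (5.55-fold). Cd7, a surface protein of T and NK cells, was listed at 0 in all 3 flox libraries and at 6.58, 7.87 and 3.96 FPKM in knockout libraries 302, 341 and 466. Pdzk1ip1 was likewise listed at 0 in flox tissue and at 5.08, 3.45 and 5.49 FPKM. None of these 6 passed the threshold (limma, adjusted p = 0.122 for each), and the same holds for all 14038 genes tested.

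The other genes named by their small p had groups that did not overlap, which their selection by p favours. On the higher side, Bckdhb stood at 550 ± 51.1 FPKM in knockout and 317 ± 11.3 in flox tissue (SD, n = 3), Tst, which encodes a mitochondrial sulfurtransferase, at 208 ± 19.6 and 90.9 ± 21.6, Sycp3, a protein of meiotic chromosomes, at 187 ± 14.1 and 111 ± 7.01, Nsdhl at 108.5 ± 18.8 and 52.2 ± 2.86, and Cd3g at 19.2 ± 4.38 and 5.72 ± 1.25. On the lower side, Thbs1 stood at 238 ± 81.7 in knockout and 715 ± 261 FPKM in flox tissue, Scn7a, a sodium channel, at 139 ± 11.2 and 276 ± 50.8, Cyp27a1, the sterol 27-hydroxylase, at 153 ± 9.87 and 216 ± 15.6, Pddc1 at 78.0 ± 4.71 and 108 ± 2.38, and Ppfibp2 at 17.1 ± 2.29 and 31.7 ± 3.84. The complement genes C4b (388 ± 18.5 and 678 ± 134 FPKM) and C4a (72.9 ± 2.90 and 126 ± 25.8) are near-identical copies whose reads may have been shared, so each is uncertain. Plcd4, a phospholipase, was listed at 0 in all knockout libraries and at 3.12, 11.8 and 9.36 FPKM in flox libraries 282, 369 and 485. These genes had adjusted p between 0.216 and 0.548 (limma).

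Over all genes, limma called 0 of 14038 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 768 of 14038 genes, where chance gives a share of 0.05, with 533 higher and 235 lower in the knockout. Under median-ratio scaling these were 462 higher and 304 lower, and under quantile normalization 489 higher and 299 lower. The groups did not overlap for 1503 genes, or 10.7% of those tested, where chance gives 10%. Limma without the mean-variance trend called 5 genes, named here because they were called, all higher in the knockout: Ncr1 (adjusted p = 0.0185), Pdzk1ip1 and 2410076I21Rik (0.0199 each), and Cd7 and Prr7 (0.0427 each). With array weights it called 3579, in a weight fit that did not converge.

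T and NK cell genes rose together in the knockout. Of the 22 tested markers 21 were higher, with a median log2 fold change of 0.84, and the list moved as a set (limma camera, adjusted p = 1.2e-14; adjusted p = 0.531 with an estimated correlation). Cd3g, a chain of the T cell receptor complex, was 3.36-fold higher. Nkg7, a protein of cytotoxic granules, stood at 23.2 ± 10.1 against 5.11 ± 1.70 FPKM (SD, n = 3), 4.54-fold higher, and Ncr1, an activating receptor of NK cells, was listed at 0 in all flox libraries and at 2.56, 2.28 and 2.35 FPKM in knockout libraries 302, 341 and 466. Of these markers 8 passed when adjusted over the list alone, all higher, and 0 when adjusted over all genes. Cd247, the most abundant of the named markers, was at 31.5 ± 1.89 and 25.3 ± 1.55 FPKM.

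B and plasma cell genes moved the other way. Of 16 tested markers 12 were lower in the knockout, with a median log2 fold change of -0.44, and the list fell as a set (limma camera, adjusted p = 0.00172; adjusted p = 0.531 with an estimated correlation). Pou2af1, a B cell coactivator, stood at 3.48 ± 0.408 FPKM against 6.83 ± 1.03 in flox tissue (SD, n = 3), and Cxcr5, a chemokine receptor of B cells, at 1.75 ± 0.432 against 3.63 ± 0.976. The joining chain of secreted immunoglobulin, Igj, was among the 4 members that were higher in the knockout, at 94.9 ± 5.59 against 55.1 ± 19.1 FPKM. In this list 0 members passed when adjusted over the list alone or over all genes.

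The list of branched-chain amino acid breakdown genes, which also holds a regulatory kinase and transporter subunits, rose in the knockout. Of 23 tested members 22 were higher, with a median log2 fold change of 0.26, and the list moved as a set (limma camera, adjusted p = 1.91e-10; adjusted p = 0.531 with an estimated correlation). Bckdhb, a subunit of the branched-chain ketoacid dehydrogenase that commits these amino acids to breakdown, was 1.73-fold higher. Both subunits of the leucine pathway enzyme methylcrotonyl-CoA carboxylase were higher, Mccc1 at 381 ± 25.4 against 257 ± 45.4 FPKM and Mccc2 at 329 ± 31.6 against 239 ± 19.4 (SD, n = 3). These 3 genes passed when adjusted over the list alone, and 0 members passed when adjusted over all genes.

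Genes of triglyceride storage and of fatty acid uptake were higher in the knockout as groups. The list of triglyceride synthesis and lipid droplet genes rose, with 14 of 18 members higher and a median log2 fold change of 0.25 (limma camera, adjusted p = 0.0166; adjusted p = 0.900 with an estimated correlation). Its score in knockout 466 (-0.05) lay below that in flox 369 (0.05), so the groups overlapped. Dgat1, which makes triglyceride from diacylglycerol, stood at 1112 ± 103 against 639 ± 177 FPKM (SD, n = 3), Plin1, which coats the adipocyte lipid droplet, at 2469 ± 45.3 against 1882 ± 113, and the seipin gene Bscl2 at 903 ± 84.5 against 635 ± 124. The fatty acid uptake list rose by a median of 0.19 with 11 of 14 members higher (limma camera, adjusted p = 0.0254; adjusted p = 0.900 with an estimated correlation). In it, Lpl, the lipase that releases fatty acids from lipoproteins, was at 15561 ± 1545 against 11295 ± 1457 FPKM, and Acsl1, an acyl-CoA synthetase, at 4942 ± 1312 against 2880 ± 948. In both lists 0 members passed when adjusted over the list alone or over all genes. Without flox replicate 282 both calls ended (limma camera, adjusted p = 0.704 for triglyceride genes and 0.295 for uptake genes), and the uptake call also ended without knockout replicate 302 (0.0638) and under quantile normalization (0.0972). Flox 282 also stood apart in cell type markers, with the highest macrophage (0.92), mesothelial (0.71), fibroblast (0.55) and extracellular matrix (0.45) scores and the lowest white adipocyte score (-0.21) of the 6 libraries.

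Cholesterol synthesis genes rose as well, with 15 of 19 members higher and a median log2 fold change of 0.08 (limma camera, adjusted p = 0.00648; adjusted p = 0.900 with an estimated correlation). Nsdhl, a sterol dehydrogenase, was 2.08-fold higher, and Cyp51, the sterol demethylase, was at 85.3 ± 31.7 against 45.4 ± 8.63 FPKM (SD, n = 3). Of the members 2 passed when adjusted over the list alone, Nsdhl among them, and 0 passed when adjusted over all genes. The call ended without flox replicate 282 (limma camera, adjusted p = 0.0768) and without knockout replicate 302 (0.0861). The cholesterol score of knockout 466 (-0.12) lay below those of flox 282 (-0.10) and flox 485 (-0.09). De novo lipogenesis did not pass as a set (limma camera, adjusted p = 0.0512, or 0.0448 with the library set as covariate; adjusted p = 0.688 with that covariate and an estimated correlation), although 19 of 24 members were higher, among them the citrate carrier Slc25a1 at 1046 ± 222 against 606 ± 114 FPKM, Thrsp at 2398 ± 501 against 1482 ± 193, and the acetyl-CoA synthetase Acss2 at 181 ± 17.2 against 124 ± 22.3.

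**Figure D2:**
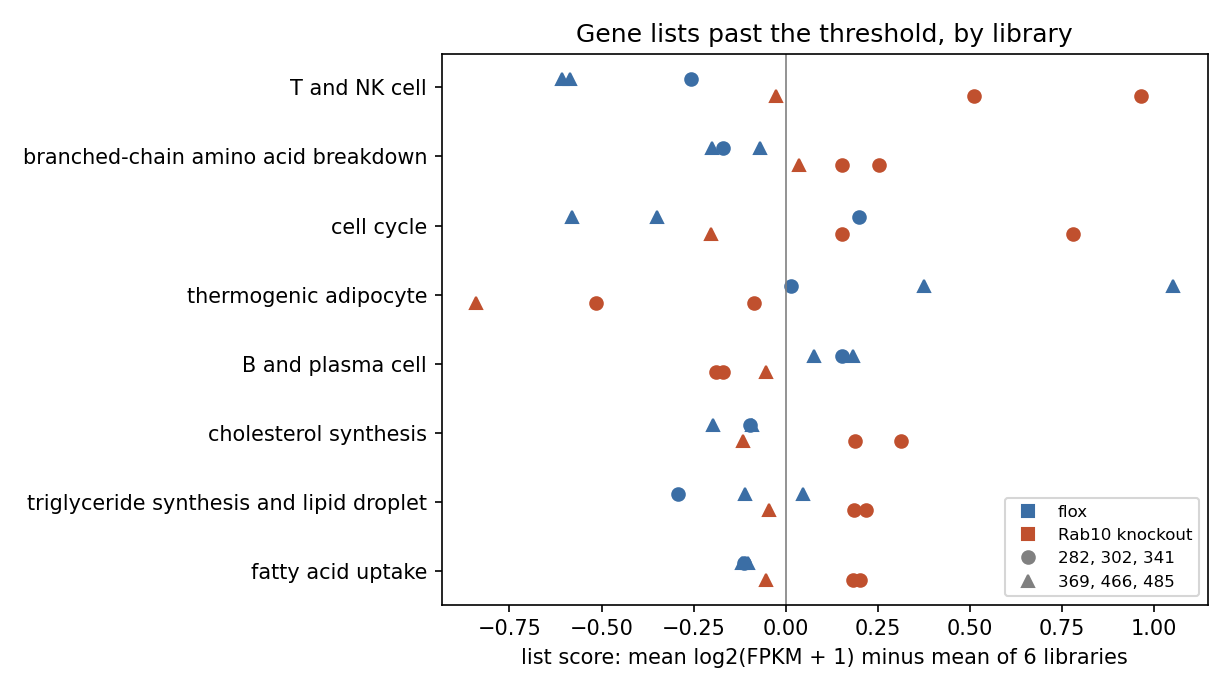
Score of each of the 8 lists past the threshold in each library: the mean over members of log2(FPKM + 1) minus the mean of the 6 libraries (horizontal axis, log2 units), in flox (blue) and knockout (orange) libraries, with circles for replicates 282, 302 and 341 and triangles for 369, 466 and 485. The T and NK cell scores run from -0.61 to -0.26 in flox and from -0.03 to 0.96 in knockout libraries, and flox 485 stands highest for thermogenic genes at 1.05.

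Thermogenic genes of brown and beige adipocytes fell in the knockout. Of 17 tested members 10 were lower, with a mean log2 fold change of -0.96 and a median of -0.15, and the list moved as a set (limma camera, adjusted p = 5.95e-04; adjusted p = 0.900 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, was at 23.7, 51.0 and 326 FPKM in flox libraries 282, 369 and 485 and was listed at 13.8, 0 and 0 in knockout libraries 302, 341 and 466. Fabp3, a fatty acid binding protein, stood at 9.58 ± 5.46 against 60.1 ± 39.1 FPKM (SD, n = 3), and Slc27a2, a fatty acid transporter, was listed at 0 in all knockout libraries and at 1.68, 6.10 and 14.9 in flox libraries 282, 369 and 485. Adjusted over the list alone, 5 members passed, all lower, and 0 passed when adjusted over all genes. Flox 485 had the highest value of each of these 3 genes, and the list stayed past the threshold without it (limma camera, adjusted p = 0.0298).

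Cell cycle genes rose, with 23 of 24 members higher and a median log2 fold change of 0.50 (limma camera, adjusted p = 4.43e-04; adjusted p = 0.900 with an estimated correlation). Their levels were low. Rrm2, a subunit of ribonucleotide reductase, stood at 5.68 ± 1.63 against 3.16 ± 0.520 FPKM (SD, n = 3) and Mcm5, part of the replicative helicase, at 6.35 ± 1.79 against 3.27 ± 1.45, and 0 members passed when adjusted over the list alone or over all genes. The call ended without knockout replicate 302 (limma camera, adjusted p = 0.0611) and among genes with a mean of at least 5 FPKM (0.0617). The extracellular matrix list did not pass as a set (limma camera, adjusted p = 0.102, or 7.47e-04 with the library set as covariate; adjusted p = 0.688 with that covariate and an estimated correlation), and its median (0.02), mean (-0.08) and test (lower) differed in sign. Thbs2 and Thbs1 passed when adjusted over that list alone, both lower, and Col5a1, a fibrillar collagen chain, was at 69.5 ± 7.73 against 94.3 ± 5.00 FPKM.

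The libraries differed in a way the genotypes do not explain. Flox 282, knockout 302 and knockout 341 correlated with each other at 0.981 to 0.988 over the tested genes, as did flox 369, knockout 466 and flox 485 at 0.981 to 0.984, while pairs across these sets lay between 0.954 and 0.974; genes are not independent replicates. The first principal component, with 53.1% of the variance, parted the 2 sets. On the next component, with 16.3%, flox libraries lay between 3.80 and 26.1 and knockout libraries between -17.0 and -14.1. Macrophage scores were 0.92, 0.52 and 0.65 in the first set and -0.26, -0.79 and -1.04 in the second. T and NK cell scores also moved with the sets: among knockout libraries 302 and 341 scored 0.51 and 0.96 and 466 scored -0.03, and among flox libraries 282 scored -0.26 and 369 and 485 scored -0.61 and -0.58. Cell cycle scores moved with the sets too: flox 282 (0.20) lay above knockout 341 (0.15) in its own set, knockout 302 stood apart at 0.78, and flox 369, knockout 466 and flox 485 scored -0.35, -0.20 and -0.58. With the set as a covariate, chosen after seeing the data, limma called 0 genes, with 1442 at an unadjusted p under 0.05; the T and NK cell, B and plasma cell, branched-chain, triglyceride, thermogenic and cell cycle lists stayed past the threshold, and the cholesterol and fatty acid uptake lists did not (limma camera, adjusted p = 0.0630 for both). With that covariate 7 further lists passed at the preset correlation (limma camera): oxidative phosphorylation (adjusted p = 1.06e-07), endothelial (0.0411) and de novo lipogenesis genes (0.0448) were higher in the knockout, and mesothelial (8.86e-05), extracellular matrix (7.47e-04), macrophage (0.00242) and fibroblast genes (0.0248) were lower. Flox 282 is the only flox library of its set. In the other set knockout 466 scored between flox 369 and flox 485 for oxidative phosphorylation, endothelial, mesothelial, macrophage and fibroblast genes. For de novo lipogenesis knockout 466 scored below both (-0.10 against -0.05 and 0.07), against the direction called. For extracellular matrix it also scored below both (-0.44 against 0.07 and -0.40), as called. With an estimated correlation and the same covariate, 0 of the 33 lists passed (limma camera, adjusted p of 0.688 or more).

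**Figure D3:**
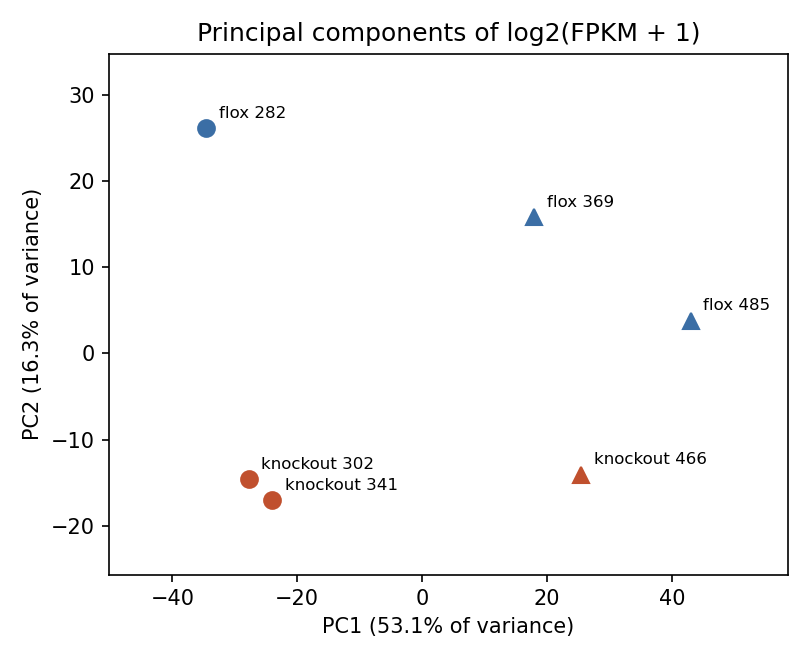
Principal components of log2(FPKM + 1) over the 14038 tested genes: PC1 (53.1% of variance) on the horizontal and PC2 (16.3%) on the vertical axis, in flox (blue) and knockout (orange) libraries. Flox 282 and knockout 302 and 341 (circles) lie at negative PC1, and flox 369 and 485 and knockout 466 (triangles) at positive PC1.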

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

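The library set as covariate, the tests of each called list by itself and the test without members listed at 0 in a whole group were chosen after the results were seen; the other settings were planned. Limma's count of 0 genes past the threshold, with 768 at an unadjusted p under 0.05, was 0 under the other scalings, filters, pseudocount, covariates, robust moderation and an adjusted p threshold of 0.1. It was 5 without the mean-variance trend (Ncr1, Pdzk1ip1, 2410076I21Rik, Cd7 and Prr7, adjusted p from 0.0185 to 0.0427). Of these, Ncr1, Pdzk1ip1 and Cd7 were listed at 0 in all flox libraries. They thus had no spread in flox and passed the filter through the knockout libraries alone. Prr7 and 2410076I21Rik must have lain at or near 0 in flox too. Their log2 fold changes rose from 1.78 and 2.13 to 4.66 and 5.12 with the pseudocount of 0.1 FPKM. That of Ncr1 rose from 1.76 to 4.64. Whether flox values at or near 0 caused the calls was not tested. The count was 3579 with array weights, whose fit did not converge and gave weights from 0.258 (flox 282) to 6.46 (flox 369). Leaving out each library gave 0 to 1 genes; the single gene, without flox 282, was C1qtnf5. The Rab10 log2 fold change stayed negative and below the threshold, from -0.45 to -0.23 with a library left out and -0.46 with the library set as covariate.

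The count of lists past the threshold, 8, was 7 to 9 under the planned scalings, filters and pseudocount, 0 with an estimated correlation, 0 by fry, 13 with the library set as covariate (0 with an estimated correlation as well), and 8 to 14 with a library left out (14 without flox 485). With an estimated correlation the adjusted p was 0.531 for the T and NK, B and plasma and branched-chain lists and 0.900 for the thermogenic, cell cycle, cholesterol, triglyceride and uptake lists. Fry gave 0.122 (B and plasma), 0.141 (T and NK), 0.174 (branched-chain), 0.592 (thermogenic, triglyceride and uptake) and 0.641 (cell cycle and cholesterol). The estimated correlations ran from 0.014 (B and plasma) to 0.54 (cell cycle), against 0.01 preset. The uptake list was at 0.0972 under quantile normalization, uptake and cholesterol at 0.0630 with the library set as covariate, and cell cycle at 0.0617 with the stricter filter; the cause was not tested. With a library left out, the adjusted p ran from 0.00132 to 0.704 for triglyceride genes, 0.00334 to 0.295 for uptake, 5.51e-04 to 0.0861 for cholesterol and 3.16e-05 to 0.0611 for cell cycle.

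Fold changes of named genes other than Rab10 were recomputed under the other pseudocount, filters and scalings, with a library left out and with the library set as covariate. A gene that failed the filter of a setting had no value there. Cd7, Pdzk1ip1, Ncr1 and Plcd4 thus had none at a mean FPKM of at least 5. Changes of the limma fit itself, such as the one without the trend, are not among these values. Of the 700 values obtained, 694 kept their direction and stayed below the threshold. The exceptions were C1qtnf5 without flox 282 (limma, adjusted p = 0.00769) and small changes of Rab genes: Rab13 ran from -0.181 to 0.0224 with a library left out, Rab8a from -0.00628 to 0.179 and Rab8b from -0.0698 to 0.514, and with the library set as covariate Rab8a was at -0.0218 and Rab8b at -0.126. No paired analysis was possible because the groups share no replicate numbers. The depth behind each FPKM is unknown, so a value listed at 0 cannot be told from one below detection.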

Other observations

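Among groups that did not move as sets, single members stood apart between the genotypes. Ccl5, a chemokine that T cells make and follow, was at 125 ± 68.0 FPKM in knockout and 39.0 ± 5.44 in flox tissue (SD, n = 3), 3.21-fold, while the acute phase gene Saa3 was at 70.8 ± 40.2 and 170 ± 37.7 FPKM; their list of inflammatory cytokines and acute phase genes did not move (limma camera, adjusted p = 0.899). The interferon response list did not move either (limma camera, adjusted p = 0.20). Gsta4, a glutathione transferase that clears lipid peroxidation products, was at 298 ± 63.4 and 174 ± 12.4 FPKM in a list of antioxidant genes that did not move (limma camera, adjusted p = 0.197). Adig, an adipocyte gene, was at 2487 ± 268 and 1751 ± 224 FPKM, Tpi1, a glycolytic enzyme, at 507 ± 35.5 and 368 ± 57.0, and Atp5g3, an ATP synthase subunit, at 3150 ± 85.4 and 2442 ± 228; the adipocyte, glycolysis and oxidative phosphorylation lists did not pass (limma camera, adjusted p = 0.546, 0.221 and 0.0935), though with the library set as covariate oxidative phosphorylation did, higher in the knockout (limma camera, adjusted p = 1.06e-07; adjusted p = 0.688 with an estimated correlation). None of these genes passed the threshold over all genes (limma, adjusted p of 0.631 or more).

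Macrophage markers varied more between libraries than between genotypes. Mpeg1 was at 201, 92.6 and 63.7 FPKM in flox libraries 282, 369 and 485 and at 189, 246 and 79.8 in knockout libraries 302, 341 and 466, and the macrophage list did not pass (limma camera, adjusted p = 0.552), except with the library set as covariate, where it was lower in the knockout (limma camera, adjusted p = 0.00242; adjusted p = 0.688 with an estimated correlation). Itgax, a marker of dendritic cells and inflammatory macrophages, was at 5.03 ± 1.97 in knockout and 2.42 ± 1.05 FPKM in flox tissue (SD, n = 3). Mylpf, a fast muscle myosin light chain, was at 38.6 FPKM in flox 369 and at most 4.14 in the other libraries. C1qtnf5, a secreted protein, was at 0.06 and 0.03 FPKM in flox 369 and 485 and between 19.4 and 24.9 in the other 4 libraries, flox 282 included.

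In the 3 patterns weighed next, these tests were chosen only after the result was seen: the count of large differences in the library split, the comparisons of the T and NK cell list and of the branched-chain list with other lists and within library sets, and the counts of splits for genes and for these 2 lists. The other tests were written before their results were seen.

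The library split, flox 282, knockout 302 and knockout 341 against the others, called 2278 genes in limma, where the split by genotype called 0, which points to a structure of the samples; the libraries were parted by the same values that were then tested. That all 10 splits of the 6 libraries gave at least as many genes as the genotype split (highest other 2278) is fixed by its count of 0 and tests nothing; 9 gave as many lists past the threshold (8 by genotype, highest other 15), and 10 splits are too few for a share under 0.05. The T and NK cell list passed in 5 and the branched-chain list in 4 of the 9 other splits (lowest adjusted p = 3.93e-05 and 3.86e-08, limma camera at the preset correlation). Both had their lowest adjusted p in the genotype split. Every other split keeps most knockout libraries on the same side, so it holds part of any genotype difference. These counts therefore cannot show whether a call of either list is specific to genotype. The scale of the libraries does not account for the library split, since 1886 calls were made after quantile normalization. A lower immune cell share alone would raise all other genes by a small common factor, whereas 125 calls were higher by over 1 on the log2 scale in flox 369, knockout 466 and flox 485. RNA other than mature mRNA, or DNA, stays open: of 331 vomeronasal and trace amine receptor genes, silent in fat, 2 to 4 were above 0 in the first set and 3 to 5 in the second, an overlap of 1 gene that meets the bound written beforehand against this explanation, but is no larger than the SD of 1.03 between libraries; olfactory receptor genes above 0, looked at afterwards, were 9, 7 and 6 (flox 282, knockout 302 and knockout 341) against 12, 11 and 11 (flox 369, knockout 466 and flox 485), which goes with it, and snoRNA genes 2, 2 and 3 against 10, 5 and 3, which touch at 3. That the spread in the receptor count would decide was settled only after the counts were seen. The labels name no batch. At the preset correlation 8 lists passed in this split, which was drawn from the same values. Skeletal muscle (limma camera, adjusted p = 0.00157) and oxidative phosphorylation genes (6.69e-09) were higher in flox 369, knockout 466 and flox 485. Macrophage (limma camera, adjusted p = 8.78e-12), mesothelial (0.00157), fibroblast (0.00213), cell cycle (0.00378), interferon (0.00413) and extracellular matrix genes (0.015) were lower there. No prediction was written for these lists, so other differences in cell make-up stay open.

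The T and NK cell list was higher in the knockout. Lymph node tissue in the dissected fat would bring B cells too, but the median log2 fold change of T and NK markers exceeded that of B and plasma markers by 1.28 (95% bootstrap interval over members, 0.79 to 1.93); the short list of lymph node stroma markers leaned the way of this explanation, with 5 of 6 members higher and a median of 0.29, and did not pass (limma camera, adjusted p = 0.249). A lower adipocyte share would raise other cell types alike, but the list exceeded the macrophage, endothelial and fibroblast lists by at least 0.57 (interval of the smallest difference, 0.29 to 1.23), and by at least 0.66 with the library set as covariate. These intervals, like those for the branched-chain list below, resample members and hold no spread between libraries. Members of the T and NK list move together (estimated correlation 0.38), so the intervals do not measure how the differences would vary between mice. The library split does not account for most of the rise: the median was 0.71 with the set as covariate, against 0.84 without. Within both library sets every knockout library scored higher than every flox library, by at least 0.56. That ordering tests nothing further, since the lowest knockout score (-0.03) exceeds the highest flox score (-0.26) over all 6 libraries. Values listed at 0 do not account for the rise either: the 16 markers above 0 in all libraries had a median of 0.82. Low values above 0 stay open, because the depth behind them is unknown. A larger number of T and NK cells in the fat of the knockout mice may be a hypothesis worth testing. The age of the mice, which the labels give for the knockout only, was left untested. The list passed the threshold only at the preset correlation, where other splits, which hold part of any genotype difference, call it too.

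The branched-chain amino acid list was higher in the knockout. The library split does not account for it, since the median was 0.26 with and without the set as covariate. Every knockout library scored higher than every flox library within both sets, by at least 0.11. That ordering tests nothing further, since the lowest knockout score (0.04) exceeds the highest flox score (-0.07) over all 6 libraries. A higher adipocyte share stays open: the list exceeded the white adipocyte list by 0.19, with a 95% bootstrap interval over members from -0.01 to 0.34. More mitochondria per cell stay open too: the list exceeded the oxidative phosphorylation list by 0.17 (0.11 to 0.28), but with the set as covariate by 0.11 (0.01 to 0.18), and in the first set the difference between these scores overlapped between genotypes. A higher expression of this pathway alone may be a hypothesis, but it cannot be told apart from a higher share of adipocytes or of mitochondria.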
